A study of Homo sapiens with 4 samples.

How the data were processed

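RNA was measured in human umbilical vein endothelial cells (HUVEC), primary cells that line a vein, after infection with an adenovirus carrying either GFP, the control, or TFEB, a transcription factor of the MiT/TFE family. Per the labels' protocols, nearly confluent cells were infected at a multiplicity of infection of 10 and collected 24 h later. Total RNA was purified on columns, and equal amounts were amplified from the 3' end, labelled with biotin and hybridised to Affymetrix expression arrays. There were 2 arrays per group and 4 in all. Nothing in the labels says whether the arrays came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical.

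The authors deposited log2 expression values per probe set, made by RMA (background correction, quantile normalization and median polish) in R 2.15.1 per the submitters' processing notes. The values came in an annotated table with gene symbols and Entrez identifiers and in a table by sample, and these differed by at most 5e-09. Columns of the annotated table name the group but not the replicate, so the table by sample was used wherever an array was left out or replicates were matched. RMA brings the arrays to nearly 1 distribution, so a general rise or fall of RNA is not visible in these values. No detection calls were used, and the number of arrays limits the precision.

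Of 54675 probe sets, 62 were control probe sets, 41910 carried 1 gene name, none carried several and 12703 carried none. The probe set with the highest mean over the 4 arrays stood for each gene, which gave 20184 genes, 10834 of them with more than 1 probe set. In 96 genes, different probe sets passed the threshold in opposite directions. Entrez identifiers matched 19556 genes to a RefSeq gene table of the assembly GRCh38.p14, which updated 2596 symbols, and the other 628 genes kept the symbol of the annotated table. That gene table was used only for names and for which genes neighbour each other. Positions of probe sets were not used here.

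Groups were compared with limma 3.58.1 (lmFit and eBayes, no intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all 20184 genes and a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 3.85. Changes are log2 differences, TFEB minus GFP, with the standard error (SE) of the moderated fit. In total, 32 gene lists with 801 genes were written before the data were examined, and 788 of these genes were measured. Members are counted at the threshold over all genes and again adjusted over the list alone. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and on ranks. Fry, which tests a list against no change and not against other genes, was run as well.

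The genes named in the text were chosen by a rule written before the data were examined: the 4 MiT/TFE genes, the 12 largest increases and the 12 largest decreases past the threshold, and up to 4 members of each list with the largest change past the threshold, or the 1 member with the largest change where none passed. The rule leaves out unnamed transcripts. After the data were in hand this was read as genes whose symbol starts with LOC, FLJ, MGC, DKFZ, HCG or PRO and a digit, which covers 762 tested genes. Among these, 99 passed the threshold and 10 of them changed at least 2-fold, 5 up and 5 down. One of them exceeds most of the 12 largest increases and is given beside them. The rule named 141 genes, of which some are not reported here.

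The procedure was tested on data simulated for TFEB against GFP over all 20184 genes. It recovered 0 of 50 genes changed 1.25-fold, 10 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 50 of 50 changed 4-fold. In that run 7 unchanged genes were called. Only 200 genes were changed there, against 28.4% of genes called in the data, and the adjusted threshold is stricter when fewer genes change. Changes down to a log2 value of 0.25 passed in the data, so these rates do not give the sensitivity of the real comparison. With no simulated change, 0 genes and 0 lists were called. A list raised 1.25-fold had a camera adjusted p of 1.75e-17 with the preset correlation and 0.489 with an estimated one. The estimated correlation thus missed this simulated shift with this number of arrays. Simulated genes were drawn independently, whereas the correlations estimated in the data ran from -0.05 for the lymphatic list to 0.43 for the mitotic list. The simulation therefore cannot show whether the preset of 0.01 overstates the calls of correlated lists. Alternatives covered the deposited table, normalization, the choice of probe set, filters on dim genes, the variance model, array weights, a replicate block, each array left out, the threshold and the list test.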

Results

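Expression was measured on 4 arrays of HUVEC, 2 infected with the GFP adenovirus and 2 with the TFEB adenovirus, to find genes that TFEB regulates in endothelial cells. Median log2 values were 4.41 and 4.39 on the GFP arrays and 4.43 and 4.44 on the TFEB arrays. Bright values were slightly lower with TFEB: upper quartiles were 6.77 and 6.82 against 6.72 and 6.70, and highest values 14.35 and 14.3 against 14.04 and 14. Over all probe sets, Pearson's r was 0.998 between the GFP arrays, 0.997 between the TFEB arrays and 0.982 to 0.984 between groups; these are correlations across probe sets, which are not independent replicates. The gap between 3' and 5' control probe sets of ACTB, a sign of RNA integrity, was 2.16 and 2.33 on the GFP arrays and 2.53 and 2.64 on the TFEB arrays. The group difference of 0.34 exceeded the largest difference within a group, 0.17. For GAPDH the groups differed by 0.02, less than the 0.09 within a group. The ACTB difference moved with the group, and so with each gene group described here. Of 45 bacterial spike-in probe sets, 3 passed the threshold, and their log2 differences ran from -0.63 to 0.30.

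Infection with the TFEB adenovirus changed 5741 of 20184 genes (28.4%), 2586 up and 3155 down. Which direction held more genes depended on the scaling: 2818 rose and 2579 fell after a second quantile normalization, and 2324 rose and 3582 fell with centred arrays. Large changes were mostly increases. TRIM63, a muscle ubiquitin ligase, rose by a log2 value of 7.73 (SE 0.07, n = 2 per group, limma adjusted p = 1.66e-06), from a mean of 3.69 to 11.42. ATP6V0D2, a subunit of the proton pump that acidifies lysosomes, rose by 7.07 (SE 0.08), and RRAGD, a Rag GTPase that signals amino acid supply to mTORC1, by 4.99 (SE 0.08). The chemokines CXCL6 and CCL2 had the largest decreases among named genes, -3.69 (SE 0.08) and -3.60 (SE 0.09).

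The other largest increases under the naming rule were SLC16A6, a transporter of the monocarboxylate family (6.67), the neurofilament genes NEFM (6.35) and NEFL (6.26), the phospholipase gene PLA1A (5.84), the transcriptional repressor BHLHE41 (5.58), NMRK2, a nicotinamide riboside kinase (5.38), CCN3 (5.09), PIK3AP1 (5.07) and ADAM7 (5.03). Their limma adjusted p-values were at most 4.36e-05. The rule passed over LOC100505564, a gene known only by a locus symbol, which rose by 6.74 (SE 0.14, limma adjusted p = 8.04e-06), more than all but TRIM63 and ATP6V0D2; it was chosen after its values were seen. A probe set without a gene name differed by 8.50, more than any named gene. The GFP level of 10 of the 12 genes lay under the median probe set, so the size of these folds depends on the background of the arrays.

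The next largest decreases were PAPPA, a protease that cleaves IGF binding proteins (-3.56), the neurotrophin gene BDNF (-3.46), GJA5, the gap junction protein connexin 40 (-3.25), the matrix gene POSTN (-3.13), CCDC85A (-3.09), the cytokine gene TNFSF18 (-3.08), LRRC17 (-2.89), the Wnt inhibitor DKK1 (-2.71), MEST (-2.56) and the collagen gene COL8A1 (-2.51). The 12 decreases had limma adjusted p-values of at most 6.33e-05. At least 2-fold changes numbered 485 up and 323 down. Fewer genes passed whichever array was left out, and each such fit has only 1 array in a group. In these fits, 0 of the 5741 changed genes had the opposite sign. Of the 808 genes that changed at least 2-fold, 798 passed whichever array was left out.

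**Figure D1:**
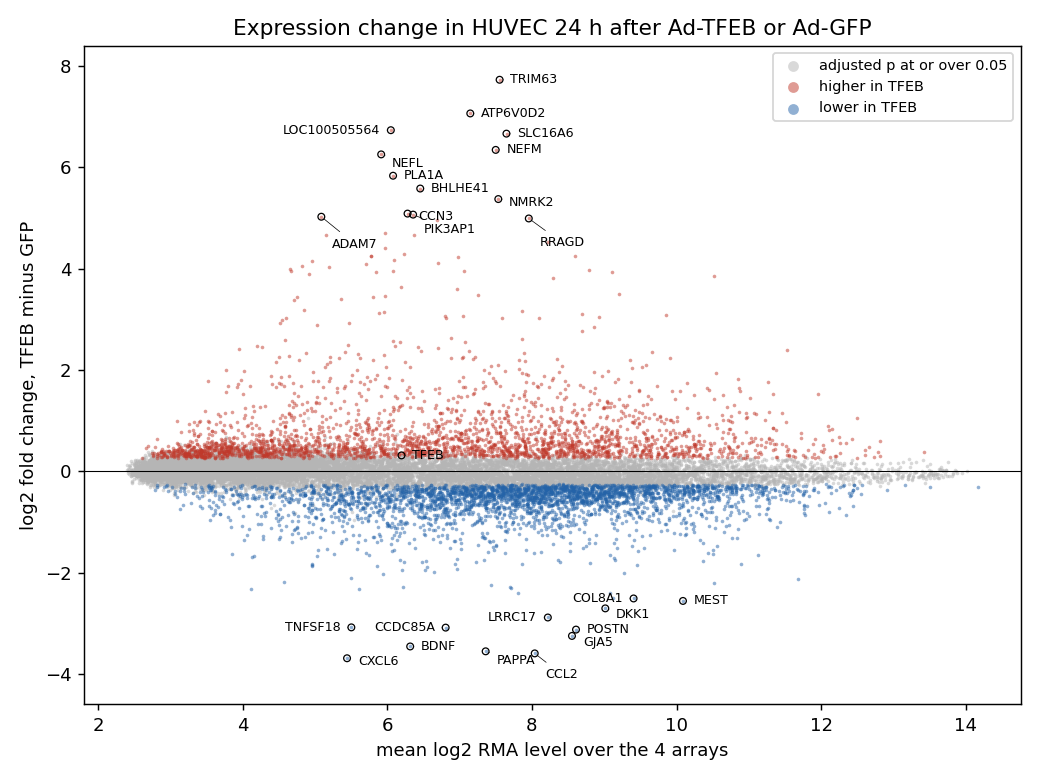
Log2 change (TFEB minus GFP, vertical) of each gene against its mean log2 RMA level over the 4 arrays (horizontal), with genes past an adjusted p of 0.05 in red (higher) and blue (lower) and the others in grey. The circled genes are TFEB, the 12 largest increases and decreases under the naming rule and LOC100505564; increases reach 7.73 and decreases -3.69.

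The probe sets of TFEB differed little between the groups. The probe set used for TFEB read 6.16 and 5.92 on the GFP arrays and 6.30 and 6.41 on the TFEB arrays, a difference of 0.31 (SE 0.11) that did not pass the threshold (limma adjusted p = 0.0746; 0.0485 without GFP replicate 1). The other TFEB probe set differed by 0.05. Whether either lies within the expressed cDNA was not determined here, so TFEB readings do not check the labels. The related genes fell: the log2 change was -0.98 (SE 0.07) for TFEC, -0.69 (SE 0.09) for MITF and -0.52 (SE 0.08) for TFE3 (limma adjusted p = 0.00520). With the mean of all its probe sets, TFE3 was at -0.17 and did not pass (limma adjusted p = 0.180).

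Genes of the lysosome rose. Of 19 subunits of the V-ATPase, the lysosomal proton pump, 14 rose and the other 5 did not pass (16 rose adjusted over the list alone), among them ATP6V1B2 (1.27), ATP6V0D1 (1.14) and ATP6V0B (1.11). Of 35 genes of the lysosomal membrane and its biogenesis, 21 rose and 3 fell (23 and 3 adjusted over the list alone). Increases there included GPNMB (3.63), the cholesterol exporter NPC1 (2.20), the calcium channel MCOLN1 (1.95) and the cystine exporter CTNS (1.81). Of 45 lysosomal hydrolases, 22 rose and 3 fell (24 and 4 adjusted over the list alone), led by the acid phosphatase ACP5 (4.52), GM2A (3.94), the protease CTSK (2.55) and the ceramidase ASAH1 (2.35). Camera adjusted p-values were 6.59e-08, 2.47e-06 and 4.12e-06 for the V-ATPase, membrane and hydrolase lists. With an estimated correlation these lists did not pass (camera adjusted p = 0.341, 0.341 and 0.492), nor did any of the 9 lists that passed with the preset. Their estimated correlations were -0.036, 0.017 and 0.105. That of the V-ATPase list lay under the preset of 0.01, so a correlation above the preset does not account for its loss. A simulated list of genes drawn independently did not pass with an estimated correlation either.

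Autophagy genes were divided. Of 43, 12 rose and 7 fell (12 and 8 adjusted over the list alone), with VPS18 (1.09), SNAP29 (0.96), VPS11 (0.81) and OPTN (0.81) changing most; VPS18, VPS11 and SNAP29 act in the fusion of vesicles with lysosomes and OPTN is a cargo receptor. The median was -0.02, the mean 0.09, and the camera direction up (adjusted p = 0.510). Of 27 regulators of Rag GTPases, folliculin and mTORC1, 8 rose and 3 fell, both over all genes and adjusted over the list alone. The largest changes besides RRAGD were FNIP2, a partner of folliculin (3.51), RRAGB (-1.06) and RRAGC (0.75). The list did not pass with the main test (camera adjusted p = 0.147) or on ranks (0.273), and its median was 0.05 against a mean of 0.39. It passed after a second quantile normalization (0.0310), with the mean of all probe sets (0.0358), in the brighter part of the genes (0.0287) and with an intensity trend (0.0216). RRAGB did not pass without TFEB replicate 1 (log2 change -1.25, limma adjusted p = 0.0520) or 2 (-0.86, 0.116). In the AMPK pathway, 3 of 16 genes rose and 4 fell (3 and 5 adjusted over the list alone; median 0.02, mean -0.05, camera direction down, adjusted p = 0.855). PRKAA1 (-0.67), STK11 (-0.58) and PRKAB2 (-0.47) fell, and TBC1D1 rose by 0.43. PRKAB2 was lost without GFP replicate 2 (0.114) and TFEB replicate 2 (0.0965), and TBC1D1 without GFP replicate 1 (0.0607) and TFEB replicate 2 (0.0616). With the mean of all probe sets, STK11 (0.304), PRKAB2 (0.0694) and TBC1D1 (0.103) did not pass.

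Endothelial identity genes fell more often than they rose, 15 against 4 of 29 (16 and 4 adjusted over the list alone; median -0.41, camera adjusted p = 0.00110; adjusted p = 0.341 with an estimated correlation). The surface receptors CLEC14A (-1.24) and ROBO4 (-0.87) and the transcription factors SOX18 (-0.88) and FLI1 (-0.86) changed most. In the brighter part of the genes the list did not pass (adjusted p = 0.0687). The ACTB gap between 3' and 5' probe sets, wider by 0.34 in the TFEB arrays, moved with this list too. Of 40 angiogenic growth factors and receptors, 9 rose and 15 fell (14 and 15 adjusted over the list alone), with a median of 0.02, a mean of -0.08 and the camera direction down (adjusted p = 0.855). The chemokine receptor CXCR4 rose by 1.76, and FGF2 (-1.40), ANGPTL4 (-1.34) and APLN (-1.27) fell. Among 19 Notch and tip cell genes, 8 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.168), with HEY1 (1.23), DLL1 (1.15) and NOTCH2 (1.09) up and ESM1 (-0.88) down. Of 17 genes that respond to shear stress or KLF2, 9 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.224; 0.0287 in the brighter part of the genes). KLF4 (2.25), CYP1B1 (1.77) and PLAT (1.71) rose, while GJA5 fell.

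**Figure D2:**
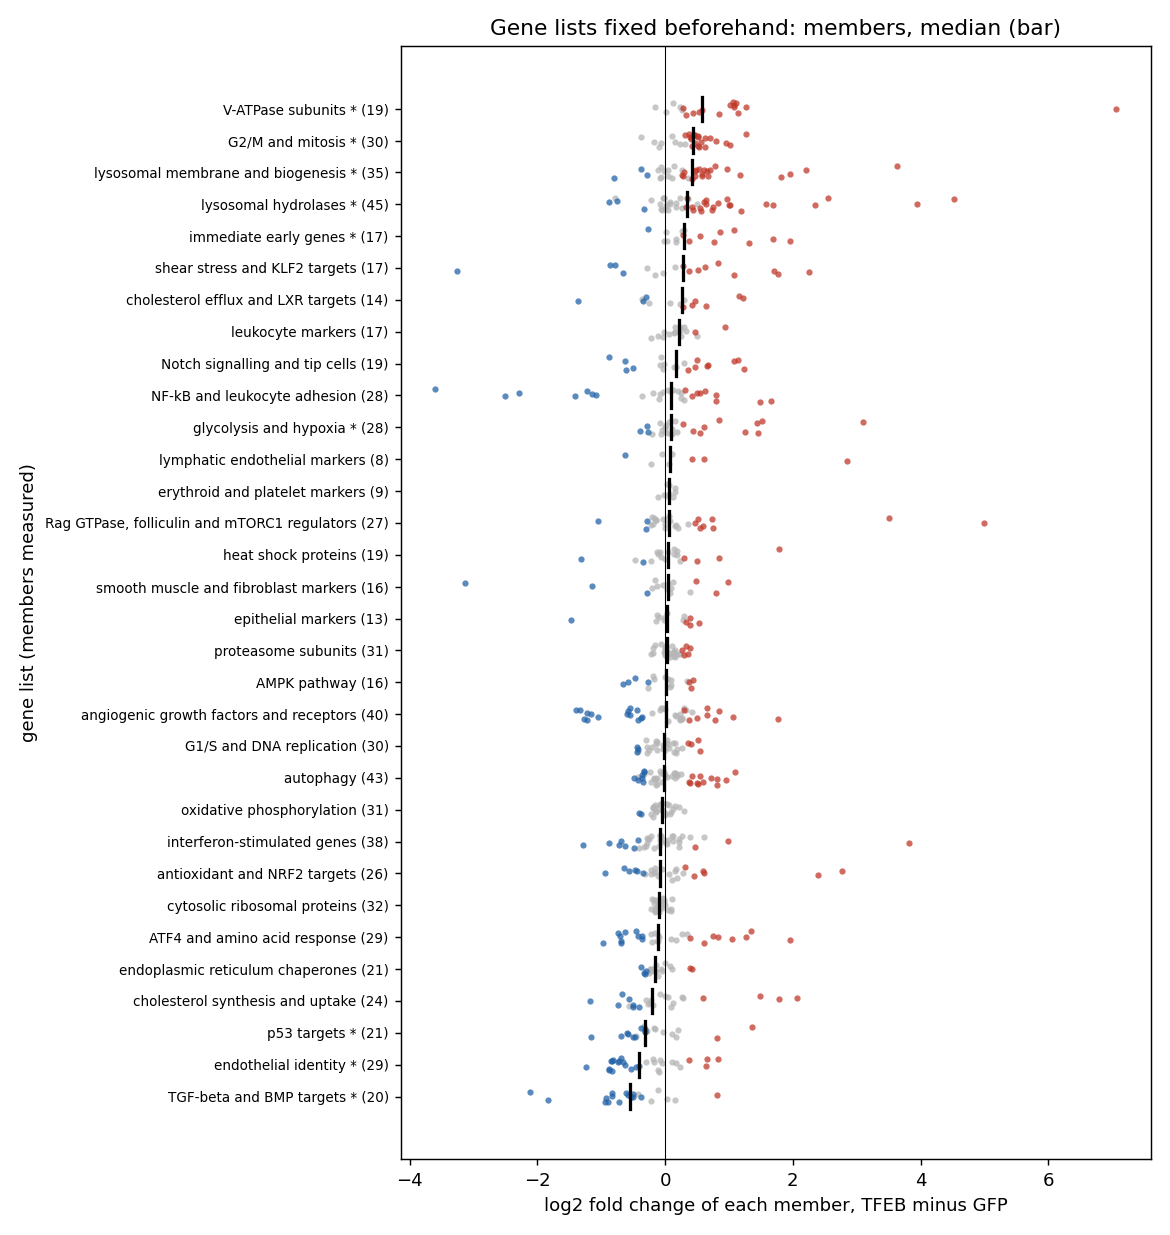
Log2 change (TFEB minus GFP) of each measured member of the 32 gene lists, a point per gene and a bar at the list's median; a star marks a camera adjusted p under 0.05 with the preset correlation. Medians of the 9 starred lists run from -0.56 for TGF-beta and BMP targets to 0.58 for V-ATPase subunits.

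Targets of TGF-beta and BMP fell, 14 of 20 with 1 rising (16 and 1 adjusted over the list alone; median -0.56, camera adjusted p = 2.47e-06; adjusted p = 0.341 with an estimated correlation). CCN2 (-2.12), CCN1 (-1.84), SMAD7 (-0.95) and SKIL (-0.93) led; SMAD7 and SKIL restrain the pathway. Immediate early genes rose, 9 of 17 with 1 falling (11 and 1 adjusted over the list alone; camera adjusted p = 1.95e-04; adjusted p = 0.341 with an estimated correlation), among them the phosphatases DUSP5 (1.96) and DUSP1 (1.08) and the transcription factors EGR2 (1.69) and JUNB (1.31). NF-kB and leukocyte adhesion genes went both ways, 9 of 28 up and 7 down (12 and 8 adjusted over the list alone), with a median of 0.10, a mean of -0.20 and the camera direction up (adjusted p = 0.885). Besides CCL2, CXCL8 (-2.51) and SELP (-2.29) fell and LIF rose (1.65). Of 38 interferon-stimulated genes, 3 rose and 7 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.445); the exonuclease ISG20 rose by 3.82 and IFITM1 by 0.98, and IFI44L (-1.29) and IFI44 (-0.87) fell.

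Mitotic genes rose, 21 of 30 (24 up and 1 down adjusted over the list alone; median 0.44, camera adjusted p = 1.52e-06; adjusted p = 0.510 with an estimated correlation), including CENPF (1.26), CENPE (1.01), BUB1 (0.96) and PLK1 (0.80). Of 30 genes of G1/S and DNA replication, 4 rose and 3 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.872). CCND1 (0.55) and CCNE1 (0.52) were among those up and CCNE2 (-0.45) among those down. Some calls were lost with fewer arrays while the change kept its sign. CCND1 was lost without GFP replicate 2 (log2 change 0.52, limma adjusted p = 0.0509). CCNE2 was lost without GFP replicate 1 (-0.40, 0.0803), GFP replicate 2 (-0.49, 0.0558) and TFEB replicate 2 (-0.34, 0.0794). CCNE1 was lost with the mean of all probe sets (0.0602). Targets of p53 fell, 10 of 21 with 2 rising (13 and 2 adjusted over the list alone; median -0.32, camera adjusted p = 0.0158; adjusted p = 0.399 with an estimated correlation). TP53INP1 (-1.16) and TNFRSF10B (-0.69) fell, and PLK3 (1.36) and GDF15 (0.81) rose. This list did not pass without TFEB replicate 2 (adjusted p = 0.0564) or among genes with a mean level of at least 5 (0.113) or in the brighter part of the genes (0.155), and TNFRSF10B did not with the mean of all probe sets (0.0663).

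Glycolysis and hypoxia genes rose in part, 10 of 28 with 3 falling, both over all genes and adjusted over the list alone (median 0.09, camera adjusted p = 0.0170; adjusted p = 0.399 with an estimated correlation; 0.0537 on ranks). NDRG1 (3.10), ENO2 (1.52), PFKFB3 (1.46) and HK2 (1.44) led. Of 24 genes of cholesterol synthesis and uptake, 4 rose and 7 fell (5 and 10 adjusted over the list alone; median -0.21, mean 0.01, camera direction down, adjusted p = 0.356). INSIG1 (2.06) and LSS (1.48) rose and MSMO1 fell (-1.18). Of 14 genes of cholesterol efflux and LXR targets, 6 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.258), with SCARB1 (1.15) and SCD (0.64) up and MYLIP (-1.36) down. Of 26 antioxidant genes, 6 rose and 6 fell (6 and 9 adjusted over the list alone; median -0.08, mean 0.13, camera direction down, adjusted p = 0.885). SOD2 (2.77) and HMOX1 (2.40) rose, and TXNRD1 (-0.93) fell. Of 29 genes of the ATF4 response, 8 rose and 10 fell (9 and 11 adjusted over the list alone; median -0.12, mean 0.07, camera direction down, adjusted p = 0.856), with CEBPB (1.96), TRIB3 (1.34), DDIT3 (1.26) and SLC7A5 (1.05) up.

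Heat shock genes gave 4 increases and 2 decreases of 19 (4 and 3 adjusted over the list alone; camera adjusted p = 0.573): CRYAB (1.78), HSPB8 (0.84) and CHORDC1 (0.50) up, HSPA1A (-1.31) down. Endoplasmic reticulum chaperones gave 2 and 4 of 21, both over all genes and adjusted over the list alone (camera adjusted p = 0.103), with HERPUD1 (0.42), DNAJB9 (0.38), HSPA5 (-0.38) and XBP1 (-0.33). That list passed, lower with TFEB, with the mean of all probe sets (0.0142) and with an intensity trend (0.0368). Of 31 genes of oxidative phosphorylation, COX5B (-0.40) and NDUFB5 (-0.38) fell, also adjusted over the list alone, and none rose (at an unadjusted limma p under 0.05, 2 were higher and 5 lower; with an intensity trend 3 and 10 passed; camera adjusted p = 0.337). Of 31 proteasome subunits, 5 rose, including PSMD2 (0.40), PSMA7 (0.36), PSMD8 (0.33) and PSMA6 (0.29), and 2 did adjusted over the list alone (camera adjusted p = 0.225; 0.0369 after a second quantile normalization and 0.0389 in the brighter part of the genes). None of 32 ribosomal protein genes passed limma's test, over all genes or adjusted over the list alone; 2 were lower at an unadjusted p under 0.05, and with an intensity trend 2 were higher and 18 lower. The ribosomal list's camera adjusted p was 0.103, but it passed, lower with TFEB, with an intensity trend (0.00404) and with the mean of all probe sets (0.0272). RPS9 had the largest difference, -0.22 (limma adjusted p = 0.0942; 0.0415 among genes with a mean level of at least 5, 0.0278 in the brighter part of the genes, 1.69e-04 with an intensity trend and 4.93e-05 with a robust one).

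Many of these small changes no longer passed with 1 array fewer, although their sign held. In the fits that lost a call, decreases ran from -0.41 (NDUFB5) to -0.28 (XBP1) and increases from 0.23 (PSMA6) to 0.41 (DNAJB9). HSPA5, XBP1, NDUFB5, PSMA7, PSMD8 and PSMA6 each lost the call whichever array was left out: without GFP replicate 1 their limma adjusted p-values were 0.0522, 0.0663, 0.0771, 0.0762, 0.0976 and 0.133, without GFP replicate 2 they were 0.0888, 0.149, 0.0579, 0.0742, 0.118 and 0.176, without TFEB replicate 1 they were 0.0507, 0.0894, 0.0622, 0.0553, 0.0525 and 0.139, and without TFEB replicate 2 they were 0.0656, 0.0796, 0.0536, 0.0638, 0.0993 and 0.0638. HERPUD1 was lost without GFP replicate 1 (0.0692) and TFEB replicate 1 (0.0622), and DNAJB9 without GFP replicate 1 (0.0829), GFP replicate 2 (0.0643) and TFEB replicate 1 (0.0714). COX5B was lost without GFP replicate 1 (0.0507), GFP replicate 2 (0.0623) and TFEB replicate 2 (0.0521), and PSMD2 without GFP replicate 1 (0.0836), TFEB replicate 1 (0.0622) and TFEB replicate 2 (0.0694). XBP1 was also lost after a second quantile normalization (0.0652) and PSMA6 with centred arrays (0.0647).

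No list of markers of other cell types passed the main camera test, though the leukocyte list passed camera in 3 alternatives. On the GFP arrays, a mean level of at least 5 was reached by 6 of the smooth muscle and fibroblast, 3 of the leukocyte, 3 of the epithelial, 5 of the lymphatic and 3 of the erythroid and platelet markers. Of the increases named below, LUM, PDGFRA, ITGAX, MS4A1, KRT5, EPCAM, ESRP1 and PDPN lay under the median probe set (4.40) on the GFP arrays. On the TFEB arrays, PDGFRA, MS4A1, EPCAM, ESRP1 and PDPN still had means of only 3.469 (MS4A1) to 4.015 (EPCAM). Of 16 smooth muscle and fibroblast markers 3 rose and 3 fell, both over all genes and adjusted over the list alone (median 0.04, mean -0.13, camera direction up, adjusted p = 0.987), with LUM (0.98) and PDGFRA (0.79) up and POSTN and COL3A1 (-1.14) down. Of 17 leukocyte markers, ITGAX (0.94) and MS4A1 (0.47) rose, also adjusted over the list alone (camera adjusted p = 0.0664; 0.0207 without GFP replicate 1, 0.0458 on ranks and 0.0478 with the replicate number as a block). Of 13 epithelial markers 4 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.490), with KRT7 (-1.47), KRT5 (0.53), EPCAM (0.40) and ESRP1 (0.39). Of 8 lymphatic endothelial markers 3 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.359), with LYVE1 (2.85), TFF3 (0.60) and PDPN (0.42) up and FLT4 (-0.63) down. None of 9 erythroid and platelet markers passed limma's test, 0 had an unadjusted p under 0.05 and 0 passed with an intensity trend; AHSP differed by 0.15 (camera adjusted p = 0.781). MS4A1 was lost without GFP replicate 2 (limma adjusted p = 0.0523), KRT5 without GFP replicate 2 (0.0829) and TFEB replicate 2 (0.0816), and PDPN without GFP replicate 1 (0.133) and TFEB replicate 2 (0.137). Without GFP replicate 2, TFEB replicate 1 and TFEB replicate 2 in turn, EPCAM (0.0985, 0.0701 and 0.0581) and ESRP1 (0.115, 0.0844 and 0.0592) did not pass. With the mean of all probe sets, PDGFRA (0.0713), MS4A1 (0.211), FLT4 (0.175) and PDPN (0.183) did not pass.

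**Figure D3:**
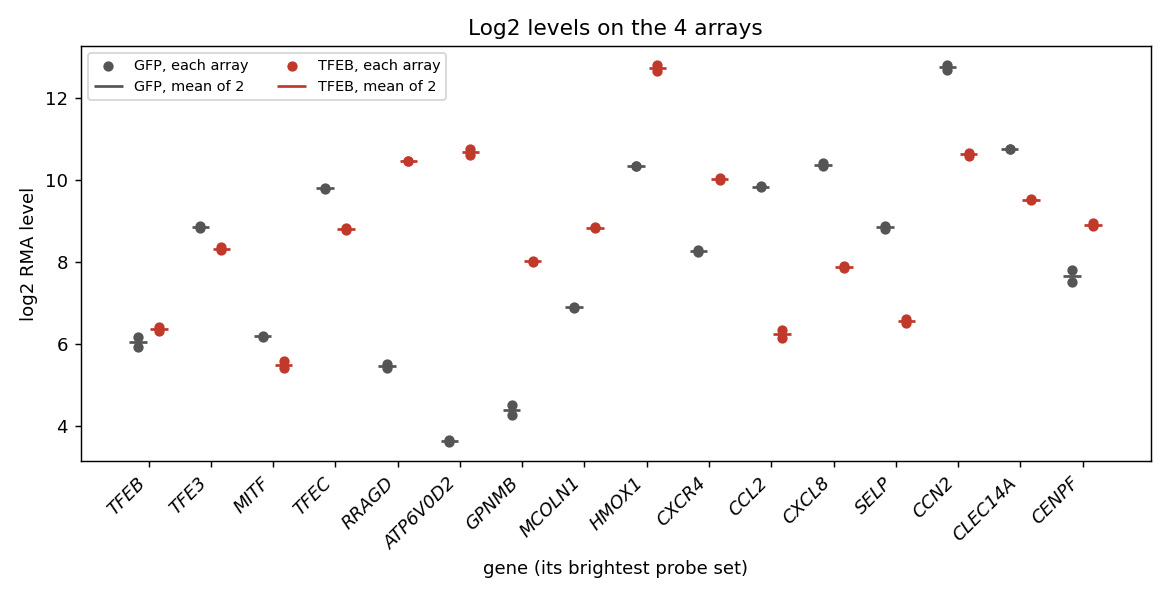
Log2 RMA value of 16 genes on each of the 4 arrays, a point per array and a bar at the mean of 2, GFP in grey and TFEB in red. ATP6V0D2 has a mean of 3.61 on the GFP arrays and 10.68 on the TFEB arrays, while the TFEB probe set lies between 5.92 and 6.41 on all 4.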

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

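Of the tests in this part, those of a general fall of bright genes and of a level-dependent shift were set before their results were seen, and the others were chosen only after the result was seen.

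Probe sets without a gene name were left out of the gene counts and lists of the report, and some differed from the GFP control. Of 12703, 576 were higher and 927 lower past the threshold, 54 of them at least 2-fold higher and 95 at least 2-fold lower, with log2 differences from -2.90 to 8.50.

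TFEB probe sets rose little on the arrays infected with TFEB, by 0.314 at most. A swap of labels is argued against by the V-ATPase list, whose lowest median on a TFEB array exceeded the highest on a GFP array by 0.55 on the log2 scale, if that list is taken as a target of TFEB. A floor or ceiling is argued against by the mean levels, the lower of which is at percentile 66.3. Probe sets that lie outside the transcribed part of the transgene cannot be told apart from a low transgene level, because probe positions were not used; the 0.314 leaves both open.

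Endothelial identity genes were lower with TFEB. A lower share of endothelial cells alone would lower the members alike, yet 25 of 29 lay more than 2 standard errors from the list's median. The spread cannot decide about a lower share that acts together with changes of single genes, because such changes would spread the members either way. A general fall of bright genes is argued against by random lists matched on level, among which the list's median of -0.41 was at percentile 0 (middle range -0.20 to 0.04), although bright genes did lie lower (median -0.0894 in the brighter part of the genes) and the list's camera call was lost against them alone (adjusted p = 0.0687). RNA quality stays open, since the ACTB gap between 3' and 5' probe sets differed by 0.339 between groups, more than within them, while that of GAPDH differed by 0.023, less than the 0.0871 within a group. An effect of TFEB remains untested beside RNA quality and a changed share of cells.

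Mitotic genes were higher with TFEB. A larger share of cells in every phase is argued against by the G1/S list, whose median was -0.0156, and a level-dependent shift by matched random lists, among which the mitotic median was at percentile 100. A chance difference in dividing cells between cultures cannot be told apart from an effect of TFEB: the list's medians per array, relative to the GFP mean, were -0.09 and 0.09 with GFP and 0.42 and 0.48 with TFEB, so the lowest TFEB array exceeded the highest GFP array by 1.88 times the largest difference within a group.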

How the results depend on the processing

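No alternative in this part was chosen after the result was seen. Against 5741 changed genes (2586 up, 3155 down), a 2-fold minimum left 808 (485 up, 323 down) and an adjusted p under 0.01 left 2845 (1288 up, 1557 down). Leaving out 1 array gave 3192 to 4013 genes (1514 to 1869 up, 1678 to 2191 down), with the lone array assumed to vary like the other group. The other alternatives stayed within 1.5 times the count, but the balance turned after a second quantile normalization (2818 up, 2579 down); with the mean of all probe sets, 65 of the 5741 genes had the opposite sign. All 139 named genes past the threshold kept their sign wherever tested, and 118 kept the call whichever array was left out. The 9 lists became 0 with an estimated correlation (4 at an unadjusted p under 0.05), 24 by fry, which does not compare a list with other genes, and 8 to 10 without 1 array. By fry, 4 lists reversed: NF-kB and adhesion (0.0114, down), antioxidant (0.0437, up), ATF4 (0.0250, up) and smooth muscle (0.0455, down), lists whose mean and camera direction differ in sign. The TFEB difference of 0.314 passed in genes with a mean level of at least 5 (adjusted p = 0.0398) and in the brighter part of genes (0.0255), where fewer genes are tested, and with a robust intensity trend (0.0449); without 1 array it ran from 0.195 to 0.434 (adjusted p 0.0485 to 0.324). The cause of the other shifts was not tested. With the replicate number as a block, 5635 genes passed (2612 up, 3023 down), 5272 of them shared, and 10 lists, leukocyte markers added (0.0478); PSMA6 was lost (0.0576). Replicate deviations correlated at -0.076 between groups over all probe sets. With 1 difference per group, this cannot show whether samples with the same number share a culture or donor. Weak signal near background limits the folds of dim genes.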

Other observations

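All tests in this part were chosen after the result was seen, as were the genes named here that the naming rule did not take.

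Decreases were enriched among CXCL chemokines, which attract leukocytes. Of 14 measured, 6 were at least 2-fold lower (42.9%, against 1.6% of all genes): CXCL6 (-3.69), CXCL8 (-2.51), CXCL11 (-2.19), CXCL1 (-1.23), CXCL2 (-1.15) and CXCL3 (-1.09). CXCL16 rose by 3.59, and the other 7 did not pass the threshold. Among 257 gene families with a shared symbol stem, tested in both directions in 514 one-sided Fisher's exact tests across genes, which are not independent replicates, this was the only one past the threshold (adjusted p = 2.22e-05). The ATP stem, which holds the V-ATPase, had 9 of 94 members at least 2-fold higher (adjusted p = 0.103).

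Several of the strongest increases lie next to each other. On chromosome 8, ADAM7 (5.03), NEFM (6.35) and NEFL (6.26) are consecutive among measured genes, with STC1 (3.86) a few genes away, while ADAM28 (0.08), ADAMDEC1 (0.01) and DOCK5 (0.13) between or beside them did not pass. On chromosome 3, PLA1A (5.84) adjoins POPDC2 (3.44), and CLEC3B (2.30), CDCP1 (3.14) and TMEM158 (3.11) are consecutive. The hypothesis that neighbouring genes may rise together was tested by permuting the calls 10000 times within bins of like level. The adjoining pairs named above prompted it and were kept in the counts, so part of the excess of higher pairs restates them. Among 15319 neighbouring pairs with no shared symbol stem and no overlap, 24 had both genes at least 2-fold higher, against a mean of 10.1 (permutation p = 5e-04, adjusted over 4 tests 0.000667), and 10 had both lower, against 4.43 (p = 0.0129, adjusted 0.0129). Over all 19487 pairs the counts were 31 higher against 12.5 and 21 lower against 5.45 (p = 1e-04 each, the smallest these permutations can give; adjusted 2e-04). These values are consistent with changes shared between neighbours; no mechanism was tested.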
